A study of Mus musculus with 96 samples.

How the data were processed

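RNA of liver, skeletal muscle, BAT and eWAT of male mice was measured on Illumina bead arrays, 96 arrays in 16 groups of 6. Per the labels, WT and SIRT1Tg mice were fed a low fat diet ad libitum, CR mice were kept on the caloric restriction named EODF for 3 months, an abbreviation that the labels do not expand, and EX mice had a running wheel for 10 weeks. Per the labels' protocols, animals were killed at 8 in the morning after 12 hours without food, and RNA was extracted with Trizol and RNeasy columns and labelled with biotin. Arrays are named as in the labels, by tissue, number and condition. That number was taken as that of the animal, which gives 27 animals, 21 of them with all 4 tissues. Numbers fall into 2 series, A (the lower numbers) and B (the higher); all EX animals are in A, all CR animals in B, and WT and SIRT1Tg have 3 animals in each. What the series stand for is not given in the sources used here. The arrays lay on 12 slides of 8 arrays. In BAT and in eWAT the SIRT1Tg arrays lay on 3 slides that held no WT array of that tissue, so condition and slide cannot be told apart within these tissues.

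The deposited signal intensity of each probe on each array, without normalisation, came from GenomeStudio per the submitters' processing notes, which also name Partek; neither version nor settings are given. The deposited series matrix holds log2 values of the same 25697 probes. Each matrix column had a median of 6.72, sorted columns differed by at most 0.0037, and each ranked its probes as its own intensity column did, so the matrix values were taken as log2 intensities after quantile normalisation over all arrays. The matrix values were used only as an alternative. All 96 columns were used.

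Values were recomputed from the intensities in R 4.3.3 with limma 3.58.1. The plan called for limma's neqc, which infers control probes from detection p-values. The deposited file holds no detection p-values and limma's own normexp fit failed on it, so the background of each array was taken as the mode of its log2 intensity density (bandwidth 0.03), followed by normexp correction with an offset of 16 and quantile normalisation within the tissue. A probe counted as detected when its intensity passed the upper 0.05 tail of that background, and probes detected on 6 or more of the 24 arrays of a tissue were kept, 13206 in liver, 12447 in muscle, 13303 in BAT and 15706 in eWAT. Gene names came from the RefSeq gene table of assembly GRCm38.p6, used for names and for which genes neighbour each other: 23962 probes were looked up by gene ID, 16 kept the platform symbol and 1719 had none. Where a gene had several probes the one with the highest mean was used, which left 9973, 9450, 10025 and 11791 features. Each of 66 further probes of named genes moved in the same direction as the probe used, 58 of them at p under 0.05.

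Each tissue was fitted over its 24 arrays with condition and number series as terms (lmFit and eBayes). SIRT1Tg, CR and EX were each compared with WT, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The number series term itself passed for 0 genes in liver (limma, with 1731 at unadjusted p under 0.05), 13 in muscle, 588 in BAT and 23 in eWAT. A fit over the 4 tissues tested by moderated F test whether an effect differed between tissues. Pairing comes from the animal: tissues of the same animal share its number, and deviations from the group means correlated between tissues of the same animal at a median of 0.0653 (-0.259 to 0.311 over 135 pairs of arrays), against -0.0108 for other animals of the condition.

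Gene lists, 34 in all, were tested with camera at a preset correlation of 0.01 and with the correlation estimated from the data, where 5 or more members were measured; p-values were adjusted over all 300 combinations of list, tissue and comparison. All are named in the report. Named are Sirt1, the 10 largest rises and 10 largest falls per comparison among genes past the threshold that kept their sign without the number series term, and up to 4 such members of each called list; where under 5 genes passed, the 5 with the smallest p are named as not past it.

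The groups, models, lists, naming rule and a set of other choices to try were fixed before the data were examined. These choices were the matrix values, no background correction, median scaling, other detection filters, the number series left out or matched, slide as a random block (correlations of 0.0872, 0.115, 0.193 and 0.117 in liver, muscle, BAT and eWAT) or fixed term, single arrays left out, the animal as a block, an estimated list correlation and WT arrays split between comparisons. Array weights, an offset of 50, removal of arrays of low detection or high in genes of another tissue, and terms for slow fibre, fast fibre and epididymis gene levels were added after the data were seen. In simulated data with 200 changed genes, recovery of 2-fold changes ran from 67.2% (eWAT CR) to 98.5% (muscle CR). For tissue differences it was 84.5% (SIRT1Tg), 79.5% (CR) and 76.5% (EX). All 12 raised lists were called. Real arrays may recover less.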

Results

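The series compared the RNA of 4 tissues of male mice under 4 conditions on Illumina bead arrays. Liver, skeletal muscle, brown adipose tissue (BAT) and epididymal white adipose tissue (eWAT) were taken from wild type (WT) mice, from mice labelled SIRT1Tg/Tg, read here as carriers of a Sirt1 transgene (SIRT1Tg), from WT mice on a caloric restriction labelled EODF for 3 months (CR), and from WT mice trained in running wheel cages for 10 weeks (EX). Each of the 16 groups held 6 arrays, 96 in all. The mean signal per array ran from 135 to 353 in liver, 153 to 278 in muscle, 225 to 282 in BAT and 213 to 365 in eWAT. Detected probes numbered 5841 to 12752 in liver, 8427 to 12321 in muscle, 11536 to 12847 in BAT and 13130 to 15381 in eWAT. The number of arrays limits the precision of every value. Fold changes are on the log2 scale against WT of the same tissue, as limma's estimate ± SE with n = 6 arrays per group, and p-values are adjusted by the Benjamini-Hochberg method. A list said to shift was called as a whole, with 0 members past the threshold unless their number is given. Where a list lost its call, brackets name the setting (1 series alone, slide as a fixed or random term, median scaling or a slow fibre term) and, for the least stable, in how many alternatives and single-array omissions the call was kept. The size of fold changes depends on the background step: without background correction the named values past the threshold were a median of 0.64 of those given (0.266 to 0.997).

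Sirt1 itself was higher in SIRT1Tg tissue, most of all in eWAT. The level rose from 7.12 ± 0.33 to 9.69 ± 0.34 in eWAT (log2 signal ± SD, n = 6), a 5.96-fold rise (adjusted p = 8.11e-13). It rose 3.57-fold in muscle, from 6.0 ± 0.13 to 7.83 ± 0.23 (adjusted p = 3.94e-10), and 2.59-fold in BAT, from 6.84 ± 0.32 to 8.22 ± 0.21 (adjusted p = 2.01e-09). In liver the difference of 0.87 ± 0.33 did not pass (adjusted p = 0.368): 5 of the 6 liver arrays labelled SIRT1Tg read 7.41 to 7.72, against 6.11 ± 0.20 in WT, and the array labelled liver_1953_SiRT1 read 4.48. That array detected 5841 probes, where the other 5 of its group detected 11631 to 12634, and without it liver Sirt1 differed by 1.38 (adjusted p = 4.46e-07). With slide as a fixed term the BAT difference of 1.11 lost its call (adjusted p = 0.162). CR and EX gave Sirt1 differences from -0.29 (liver, CR) to 0.19 (liver, EX), none of which passed. Without the array of 4.48 these 2 were -0.05 and -0.06. The size of the Sirt1 rise differed between the 4 tissues (limma F test, adjusted p = 4.4e-05).

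**Figure D1:**
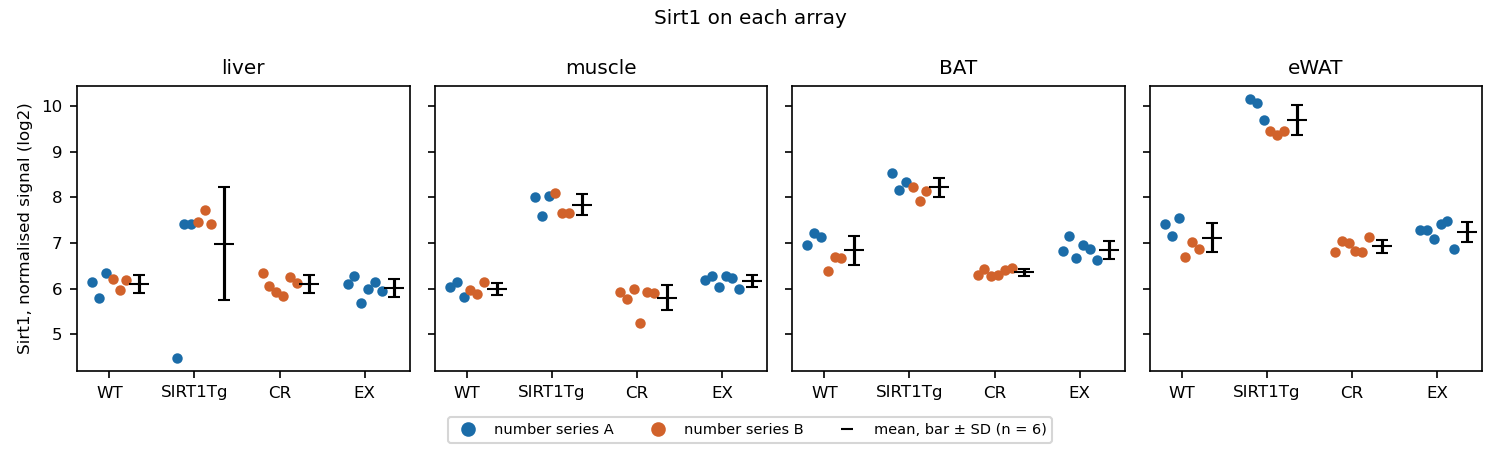
Normalised Sirt1 signal (log2) on each of the 96 arrays, by tissue and condition. Points are arrays coloured by the series of the animal number, and the bar is the mean ± SD of 6 arrays. In muscle, BAT and eWAT each SIRT1Tg array lies above every WT, CR and EX array of the tissue, and 1 liver array labelled SIRT1Tg reads 4.48.

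**Figure D2:**
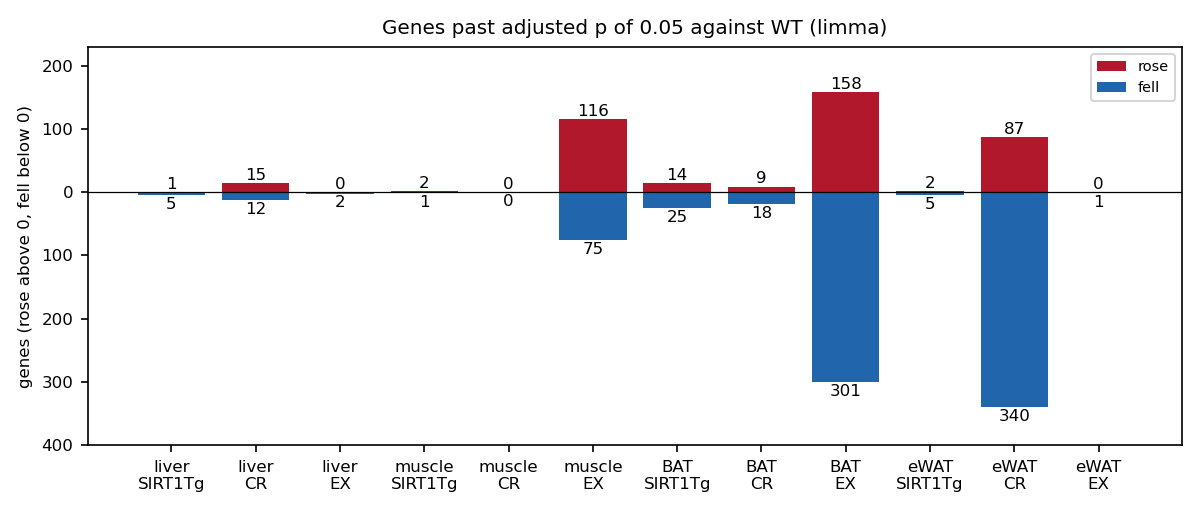
Number of genes past an adjusted p of 0.05 in each tissue and comparison with WT, with genes that rose drawn upward and genes that fell drawn downward from 0.

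In SIRT1Tg liver, 6 of 9973 genes passed, of which 1 rose and 5 fell. Orm2, an acute phase plasma protein, fell (-1.95 ± 0.34, adjusted p = 0.0331), and F11, a coagulation factor made in liver, fell (-1.06 ± 0.19, adjusted p = 0.0359). Abhd12, a lipase, fell by 0.63 and Ldb2, a cofactor of LIM domain proteins, rose by 0.60. The other 2 changes were probes without a gene symbol. All 4 named genes lay on the fitted side of WT on each of the 6 arrays. Among the fixed gene lists, the interferon response genes had a median of -0.69 with 0 of 29 members above 0. Of these members 0 changed over all genes tested and 10 fell adjusted over the list alone, and the list test (limma's camera) gave adjusted p = 3.97e-14, adjusted p = 0.337 with an estimated correlation. In the list for acute phase and innate inflammation, 1 fell over all genes tested and 1 rose and 9 fell adjusted over the list alone of 23 genes (median -0.47, adjusted p = 5.52e-09, adjusted p = 0.0898 with an estimated correlation). In liver, lymphocyte genes, macrophage and antigen presentation genes and immediate early genes shifted down (medians -0.25, -0.39 and -0.22, adjusted p = 0.00137, 0.0492 and 0.0415, or 0.49, 0.794 and 0.504 with an estimated correlation). The lists for heat shock genes, oxidative phosphorylation, fatty acid oxidation and PPAR targets and bile acid and xenobiotic metabolism shifted up (medians 0.20, 0.11, 0.11 and 0.15, adjusted p = 0.000709, 3.99e-07, 0.00336 and 0.00378, or 0.229, 0.37, 0.53 and 0.229 with an estimated correlation). Endothelial and angiogenesis genes, antioxidant and NRF2 genes and female-biased liver genes shifted up (medians 0.16, 0.14 and 0.13, adjusted p = 0.00158, 0.0422 and 0.0412, or 0.356, 0.353 and 0.37 with an estimated correlation). The array of low detection had an oxidative phosphorylation level of 10.92 against 10.29 to 10.42 on the other 5 SIRT1Tg arrays, and without it the shifts of oxidative phosphorylation, immediate early genes and antioxidant and NRF2 genes did not pass (adjusted p = 0.167, 0.11 and 0.25). Under median scaling the median of oxidative phosphorylation turned to -0.02, and the count became 1 rise and 20 falls; with the deposited matrix values it was 4 rises and 10 falls, without background correction 3 rises and 5 falls, and with an offset of 50 in the background step 3 rises and 6 falls. List calls ended for female-biased liver genes (series A, series B, fixed slide, 8 of 14 and 6 of 12), bile acid and xenobiotic metabolism (series A, median scaling), macrophage and antigen presentation genes (series A, 12 of 14 and 5 of 12) and lymphocyte genes (series A, median scaling). So did those for immediate early genes (series A, median scaling, 5 of 14 and 6 of 12), oxidative phosphorylation (series B, median scaling), endothelial and angiogenesis genes (series B, fixed slide) and heat shock genes (series B, median scaling). So did those for antioxidant and NRF2 genes (series B, fixed slide, median scaling, 5 of 14 and 6 of 12) and fatty acid oxidation and PPAR targets (median scaling). The liver SIRT1Tg count was 0 (limma, with 632 at unadjusted p under 0.05) within number series A, 6 (4 up, 2 down, 0 of them shared with the 6 above) within number series B and 7 with slide as a random block. It was 113 with slide as a fixed term (21 up, 92 down), in a joint fit giving 132 without it. Single-array omissions moved it to 0 without liver_2231_WT, 1 without liver_1955_SiRT1, liver_2207_SiRT1, liver_2222_SiRT1, liver_1959_WT or liver_2226_WT, 12 without liver_1961_WT, 21 without liver_1953_SiRT1, and the 0 came with 835 genes at unadjusted p under 0.05.

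CR changed 27 liver genes, 15 up and 12 down. The falls included Fgf21, a liver hormone of the fasting response (-2.21 ± 0.35, adjusted p = 0.00483), the lipid droplet protein Plin4 (-2.07 ± 0.30, adjusted p = 0.00169), and Pdk4, an inhibitor of pyruvate dehydrogenase (-1.71 ± 0.37, adjusted p = 0.0465). The rises included the cytochrome P450 genes Cyp2b23 (2.64 ± 0.45, adjusted p = 0.0107, 1.14 without background correction), detected on 3 WT arrays, and Cyp2a5 (1.39). Acaca, the acetyl-CoA carboxylase that commits carbon to fatty acid synthesis, rose (0.98 ± 0.19, adjusted p = 0.0265). All 20 named genes past the threshold lay on the fitted side of WT on each of the 6 arrays. The other named rises were Slc39a4, a zinc importer (1.87), Ciart, a repressor of the circadian clock (1.61, detected on 3 WT arrays), Ell3 (0.98, 3 WT arrays), Cyp2g1 (0.95, 1 WT and 5 CR arrays), the sterol transporter gene Abcg5 (0.90), the vitamin transporter gene Slc5a6 (0.87) and Nipa1 (0.75, 4 WT arrays). The other named falls were Lamb3 (-1.65), the fatty acid elongase Elovl3 (-1.45), Nat8 (-1.19), Tgoln1 (-1.04), Cyp8b1 of bile acid synthesis (-0.99), the heat shock protein Hsph1 (-0.92) and Rtp3 (-0.68).

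Of the 34 liver genes of fatty acid oxidation and PPAR targets, 2 fell over all genes tested and 5 fell adjusted over the list alone under CR, and the list had a median of -0.31 (adjusted p = 1.69e-14, adjusted p = 0.16 with an estimated correlation). In the de novo lipogenesis list 1 rose over all genes tested and 8 rose adjusted over the list alone of 20 (median 0.33, adjusted p = 4.32e-09, adjusted p = 0.162 with an estimated correlation). For the circadian clock genes 1 rose over all genes tested and 7 rose and 2 fell adjusted over the list alone of 18 (median 0.37, adjusted p = 0.00336, adjusted p = 0.37 with an estimated correlation). Among 15 heat shock genes 1 fell over all genes tested and 4 fell adjusted over the list alone (median -0.34, adjusted p = 1.16e-06, adjusted p = 0.104 with an estimated correlation). In liver, male-biased liver genes, adipocyte lipid storage genes and ER stress and integrated stress response shifted down (medians -0.32, -0.37 and -0.12, adjusted p = 0.00453, 0.000494 and 0.015, or 0.448, 0.0898 and 0.229 with an estimated correlation, with 1, 1 and 1 members past the threshold). The lists for acute phase and innate inflammation and erythroid genes shifted down (medians -0.06 and -0.32, adjusted p = 0.0431 and 0.0485, or 0.49 and 0.388 with an estimated correlation). Cell cycle genes, collagen and extracellular matrix and female-biased liver genes shifted up (medians 0.20, 0.18 and 0.08, adjusted p = 0.000147, 0.000494 and 0.015, or 0.32, 0.37 and 0.32 with an estimated correlation, with 0, 0 and 1 members past the threshold). Median scaling left 3 rises and 6 falls. List calls ended for acute phase and innate inflammation (series B, fixed slide), male-biased liver genes (fixed slide), adipocyte lipid storage genes (fixed slide) and erythroid genes (fixed slide, random slide, 5 of 12 and 5 of 12). The liver CR count was 88 (17 shared) within series B and 27 with slide as a random block. It was 30 with slide as a fixed term (9 up, 21 down), in a joint fit giving 47 without it. The liver CR count moved with single arrays, to 5 without liver_2231_WT, 7 without liver_2226_WT, 8 without liver_2232_WT, 10 without liver_2241_CR, 12 without liver_2242_CR or liver_2245_CR, 17 without liver_1960_WT, liver_2230_CR or liver_2239_CR, 42 without liver_2236_CR.

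After EX, 2 liver genes fell and 0 rose, and both encode acute phase proteins. Saa1 fell (-3.10 ± 0.54, adjusted p = 0.0369) and Orm2 fell (-2.17 ± 0.38, adjusted p = 0.0369), each on the lower side on all 6 arrays. The 3 genes of next smallest p did not pass: Bhlhb9 differed by -0.91 (adjusted p = 0.107), Zfp280d by 0.77 (adjusted p = 0.115) and Saa2 by -2.63 (adjusted p = 0.147). In the list for acute phase and innate inflammation, 2 fell over all genes tested and 6 fell adjusted over the list alone of 23 (median -0.21, adjusted p = 6.01e-05, adjusted p = 0.229 with an estimated correlation). In liver, immediate early genes, oxidative phosphorylation and male-biased liver genes shifted down (medians -0.33, -0.07 and -0.14, adjusted p = 0.00238, 0.0215 and 0.0268, or 0.356, 0.73 and 0.539 with an estimated correlation). The list for heat shock genes shifted up (median 0.16, adjusted p = 0.0283, or 0.417 with an estimated correlation). At unadjusted p under 0.05 there were 860 genes, against 498.6 by chance. In liver, calls ended for male-biased liver genes (series A, fixed slide, median scaling, 6 of 13 and 8 of 12), oxidative phosphorylation (series A, fixed slide, median scaling, 4 of 13 and 8 of 12) and heat shock genes (median scaling). The liver EX count was 1 (1 shared) within series A and 2 with slide as a random block. It was 37 with slide as a fixed term (26 up, 11 down), in a joint fit giving 19 without it. The 2 calls ended in limma (0 genes) with the matrix values, without background correction, without the detection filter, with an offset of 50, without the number series term and with array weights. Single-array omissions ended the 2 calls in limma, with 0 without liver_1959_WT, liver_2226_WT, liver_1960_WT, liver_1966_EX, liver_1969_EX, liver_1972_EX, liver_1974_EX or liver_1976_EX, at 398 to 833 genes of unadjusted p under 0.05.

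In SIRT1Tg muscle 3 of 9450 genes passed. Beside Sirt1, Dnajc12, a co-chaperone gene, rose (0.67 ± 0.10, adjusted p = 0.00332), and Maged2 fell by 0.59 (adjusted p = 0.0316), each on all 6 arrays. Maged2 kept its call in 2 of 12 single-array omissions and Dnajc12 in 12. Sgk1, a kinase gene induced by glucocorticoids, differed by 0.80 (adjusted p = 0.102) and Rhob by 0.69 (adjusted p = 0.116), and neither passed. The slow fibre genes, which encode contractile and calcium handling proteins of oxidative fibres, had a median of 1.13; 0 changed over all genes tested and 4 rose adjusted over the list alone of 13 (adjusted p = 6.77e-06, adjusted p = 0.37 with an estimated correlation). Macrophage and antigen presentation genes, lymphocyte genes and interferon response genes shifted down (medians -0.18, -0.12 and -0.15, adjusted p = 0.00187, 0.0132 and 0.00347, or 0.57, 0.371 and 0.539 with an estimated correlation). In muscle, fatty acid oxidation and PPAR targets, oxidative phosphorylation, glucose uptake and endurance genes and endothelial and angiogenesis genes shifted up (medians 0.22, 0.07, 0.16 and 0.25, adjusted p = 3.65e-05, 1.4e-05, 0.00294 and 3.65e-05, or 0.49, 0.352, 0.468 and 0.338 with an estimated correlation). The lists for heat shock genes, immediate early genes, FoxO and atrophy genes and erythroid genes shifted up (medians 0.25, 0.22, 0.11 and 0.31, adjusted p = 0.000298, 8.26e-05, 0.0145 and 0.00503, or 0.32, 0.301, 0.49 and 0.388 with an estimated correlation). WT arrays of series A were low in slow fibre genes (6.12 against 7.49 in series B). Calls ended for macrophage and antigen presentation genes (series A), lymphocyte genes (series A, fixed slide), interferon response genes (series A) and erythroid genes (series A). So did those for fatty acid oxidation and PPAR targets (series B, slow fibre term), oxidative phosphorylation (series B), slow fibre genes (series B, slow fibre term) and FoxO and atrophy genes (series B, fixed slide, slow fibre term). So did those for glucose uptake and endurance genes (series B, slow fibre term), endothelial and angiogenesis genes (series B), immediate early genes (series B) and heat shock genes (fixed slide). The muscle SIRT1Tg count was 37 (2 shared) within series A, 1 (1 shared) within series B and 3 with slide as a random block. It was 2 with slide as a fixed term (1 up, 1 down), in a joint fit giving 7 without it.

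CR left 0 of 9450 muscle genes past the threshold in limma, with 578 at unadjusted p under 0.05 against 472.5 by chance. The 5 genes of smallest p, none past the threshold, were Sel1l3 (0.62, adjusted p = 0.0914), the dynein light chain gene Dynll1 (0.77, adjusted p = 0.0914), the growth factor gene Igf2 (0.60, adjusted p = 0.12), Fbxo32, a ubiquitin ligase gene of muscle atrophy (-0.92, adjusted p = 0.12), and Ccn5 (-0.96, adjusted p = 0.12). In the de novo lipogenesis list 0 changed over all genes tested and 6 rose adjusted over the list alone of 19 (median 0.32, adjusted p = 8.96e-09, adjusted p = 0.229 with an estimated correlation). For FoxO and atrophy genes, 0 changed over all genes tested and 3 fell adjusted over the list alone of 24 (median -0.15, adjusted p = 0.00271, adjusted p = 0.413 with an estimated correlation). Macrophage and antigen presentation genes shifted down (median -0.25, adjusted p = 9.57e-05, or 0.486 with an estimated correlation). In muscle, slow fibre genes, oxidative phosphorylation and endothelial and angiogenesis genes shifted up (medians 0.83, 0.11 and 0.10, adjusted p = 0.000581, 4.74e-06 and 0.0109, or 0.468, 0.337 and 0.527 with an estimated correlation). Recovery in simulated data, 98.5% at 2-fold and 67.2% at 1.5-fold, need not hold here. Calls ended for slow fibre genes (series B, slow fibre term) and endothelial and angiogenesis genes (series B, fixed slide, slow fibre term). The muscle CR count was 2 (0 shared) within series B and 0 with slide as a random block. It was 4 with slide as a fixed term (1 up, 3 down), in a joint fit giving 4 without it. Omitting single muscle arrays gave 1 without muscle_1959_WT, 2 without muscle_1961_WT or muscle_2245_CR.

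EX changed 191 muscle genes, 116 up and 75 down, and genes of slow oxidative fibres rose most. Myl3 and Myl2, light chains of slow muscle myosin, rose by 6.58 ± 1.19, adjusted p = 0.0113 and 5.28 ± 1.12, adjusted p = 0.0174; the slow troponin genes Tnnc1 and Tnnt1 rose by 4.88 ± 1.04, adjusted p = 0.0176 and 4.78 ± 1.0, adjusted p = 0.0164. Atp2a2, the calcium pump of slow fibres, rose 5.12-fold and Myoz2 5.16-fold. Of 13 slow fibre genes, 9 rose over all genes tested and 11 rose adjusted over the list alone (median 2.25, adjusted p = 1.49e-13, adjusted p = 0.162 with an estimated correlation). The mean slow fibre level was 9.17 ± 0.54 after EX (SD, n = 6), 6.12 ± 0.13 on the WT arrays of the same number series (n = 3) and 7.49 ± 1.0 on those of the other series (n = 3). Respiratory chain genes moved alike: 8 rose over all genes tested and 19 rose adjusted over the list alone of 59, among them Atp5o (0.73), Cyc1 (0.62), Atp5g1 (0.60) and Ndufa10 (0.53), with a list median of 0.26 (adjusted p = 1.06e-16, adjusted p = 0.0898 with an estimated correlation). In the list for fatty acid oxidation and PPAR targets, 3 rose over all genes tested and 13 rose adjusted over the list alone of 28, led by Cpt2 (0.70), Acads (0.64) and Eci1 (0.60), enzymes of mitochondrial fat oxidation (median 0.55, adjusted p = 5.45e-11, adjusted p = 0.32 with an estimated correlation). For glucose uptake and endurance genes, 3 rose and 2 fell over all genes tested and 7 rose and 3 fell adjusted over the list alone of 25; the nuclear receptor gene Esrrb (1.55), the growth factor gene Vegfb (0.70) and myoglobin, Mb (0.68), rose and the potassium channel subunit Kcnab1 fell (-1.02). That list had a median of 0.32 (adjusted p = 0.00455, adjusted p = 0.49 with an estimated correlation). Among 19 endothelial and angiogenesis genes, 2 rose over all genes tested and 9 rose adjusted over the list alone, the receptor genes Flt1 (0.79) and Tie1 (0.62, detected on 5 WT arrays) (median 0.39, adjusted p = 1.4e-05, adjusted p = 0.32 with an estimated correlation).

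The other named rises in muscle were Dgat2 of triglyceride synthesis (1.93), Smtnl1 (1.81), Tnni1 (1.62, detected on 1 WT and 5 EX arrays) and Lrrc52 (1.55, 1 WT array), which were at 0.64 and 0.57 and did not pass without background correction. Falls were led by Dkk3, a secreted Wnt modulator (-1.82 ± 0.46, adjusted p = 0.0408), Gdap1 of the mitochondrial outer membrane (-1.24 ± 0.24, adjusted p = 0.0121) and Fbp2, the muscle fructose bisphosphatase (-1.05 ± 0.19, adjusted p = 0.0113). Dupd1 (-1.17), Il12a (-1.13), Tiam1 (-1.0), Ptx3 (-0.92, detected on 5 EX arrays), Twist1 (-0.86, 2 EX arrays) and Cbr2 (-0.86) fell too. All 32 named genes past the threshold lay on the fitted side on each of the 6 arrays. Myl3 was detected on 4 and Tnnc1 on 5 WT arrays, and muscle_2226_WT read 11.33 for Myl3 where the other 5 WT arrays read 4.19 to 6.81. List calls ended for fatty acid oxidation and PPAR targets, slow fibre genes, glucose uptake and endurance genes and endothelial and angiogenesis genes (slow fibre term in each). The muscle EX count was 365 (148 shared) within series A and 220 with slide as a random block. It was 304 with slide as a fixed term (205 up, 99 down), in a joint fit giving 205 without it. The muscle EX count depended on single arrays: 2 without muscle_1959_WT, 52 without muscle_1960_WT, 61 without muscle_1974_EX, 76 without muscle_1969_EX, 77 without muscle_1961_WT, 109 without muscle_1970_EX, 110 without muscle_1972_EX. With the slow fibre level as a term, chosen after the data were seen, 0 genes passed in limma, with 478 at unadjusted p under 0.05, and Myl2, Myoz2 and Smtnl1 turned to -0.08, -0.09 and -0.06. In that fit the means of the lists for fatty acid oxidation and PPAR targets and glucose uptake and endurance genes turned to -0.04 and -0.02, while oxidative phosphorylation kept its call (mean 0.19).

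In SIRT1Tg BAT 39 of 10025 genes passed, 14 up and 25 down. Sfxn1, which encodes a mitochondrial serine transporter, fell 7.25-fold, from 11.39 ± 0.26 to 8.53 ± 0.37 (log2 signal ± SD, adjusted p = 2.4e-12). Dlk1, the preadipocyte factor gene, rose (1.20 ± 0.19, adjusted p = 0.00711), and the hexokinase gene Hk2 rose by 0.65 ± 0.13. Sncg, gamma-synuclein, fell by 1.51 (adjusted p = 0.035) and the matrix proteoglycan Lum by 1.06 (adjusted p = 0.035). The other named rises ran from 0.48 (Ildr1) to 0.96 (Pnkd) and included Ankrd10, Kazald1, Gramd4, Spns1 and Slc4a8; Kazald1 was detected on 2 and Gramd4 on 3 of the WT arrays. Other named falls were Lgals3bp (-0.87), the tetraspanin Cd63 (-0.86), the NADPH oxidase subunit Cyba (-0.79), Serpinf1 (-0.74), Apobec1 (-0.72), Slamf9 (-0.70) and Casp1 (-0.68). All 20 named genes lay on the fitted side on each of the 6 arrays. Of 23 macrophage and antigen presentation genes, 0 changed over all genes tested and 14 fell adjusted over the list alone (median -0.43, adjusted p = 1.24e-08, adjusted p = 0.352 with an estimated correlation). In the list for collagen and extracellular matrix, 1 fell over all genes tested and 1 rose and 15 fell adjusted over the list alone of 30 (median -0.34, adjusted p = 4.49e-07, adjusted p = 0.299 with an estimated correlation). The lists for interferon response genes and cell cycle genes shifted down (medians -0.34 and -0.17, adjusted p = 8.96e-09 and 0.000938, or 0.299 and 0.229 with an estimated correlation). Endothelial and angiogenesis genes, heat shock genes and oxidative phosphorylation shifted up (medians 0.19, 0.23 and 0.04, adjusted p = 0.00162, 0.00336 and 0.00811, or 0.428, 0.393 and 0.429 with an estimated correlation). Fast fibre genes, markers of muscle, had a median of -1.14 (adjusted p = 0.108) with 1 of 17 above 0, at 9.27 on BAT_2222_SiRT1 against 5.03 to 6.57 on the other 5 SIRT1Tg arrays, and with their level as a term 22 genes passed. In BAT, calls ended for oxidative phosphorylation (series A, fixed slide), cell cycle genes (series B, fixed slide) and heat shock genes (fixed slide). The BAT SIRT1Tg count was 2 (2 shared) within series A, 2 (2 shared) within series B and 7 with slide as a random block. It was 2 with slide as a fixed term (0 up, 2 down), in a joint fit giving 20 without it. Leaving out BAT arrays gave 4 without BAT_2207_SiRT1, 8 without BAT_1955_SiRT1 or BAT_2231_WT, 12 without BAT_1953_SiRT1, BAT_2222_SiRT1 or BAT_1961_WT, 14 without BAT_2223_SiRT1, 23 without BAT_2226_WT, 157 without BAT_1959_WT.

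CR changed 27 BAT genes, 9 up and 18 down. Hilpda, a lipid droplet protein, fell (-1.79 ± 0.35, adjusted p = 0.0233), Btc, a ligand of the EGF receptor, fell (-1.09 ± 0.16, adjusted p = 0.00165), and Gabarapl1 of the autophagosome fell by 0.86 (adjusted p = 0.00154). Snhg11, a noncoding RNA host gene, rose (1.57 ± 0.30, adjusted p = 0.0187), and the transferrin receptor gene Tfrc rose (1.28 ± 0.23, adjusted p = 0.0137). The glycolytic aldolase gene Aldoc rose by 0.92 (detected on 3 WT arrays), C1qtnf4 by 0.86, Entpd4 by 0.81, Stard10 by 0.46, Gpsm1 by 0.43 (1 WT array), Hemk1 by 0.38 and 6430571L13Rik by 1.19. Falls of Tiam1 (-1.06), Snx24 (-0.83), Osbpl6 (-0.80), Ldhd (-0.66), Twist1 (-0.59), Zfp30 (-0.59, 5 CR arrays) and Mknk2 (-0.58) completed the named genes, all 20 on the fitted side on each of the 6 arrays. Pdk4 (-0.56) was the member that fell in the list for fatty acid oxidation and PPAR targets, where 1 fell over all genes tested and 3 fell adjusted over the list alone of 34 (median -0.15, adjusted p = 0.00144, adjusted p = 0.37 with an estimated correlation). In BAT, erythroid genes shifted down (median -0.70, adjusted p = 0.00347, or 0.352 with an estimated correlation). The lists for de novo lipogenesis and cholesterol synthesis shifted up (medians 0.17 and 0.18, adjusted p = 0.0136 and 0.00472, or 0.543 and 0.338 with an estimated correlation). An offset of 50 in the background step gave 7 rises and 24 falls. Calls ended for de novo lipogenesis (series B, fixed slide, median scaling) and fatty acid oxidation and PPAR targets (fixed slide). The BAT CR count was 13 (11 shared) within series B and 31 with slide as a random block. It was 7 with slide as a fixed term (4 up, 3 down), in a joint fit giving 12 without it. Without BAT_2230_CR and BAT_2241_CR, whose fast fibre gene levels were high, 7 genes passed; omitting single BAT arrays from the CR comparison gave 9 without BAT_2231_WT, 10 without BAT_2232_WT, 11 without BAT_2239_CR, 12 without BAT_2226_WT, 14 without BAT_2242_CR, 15 without BAT_2241_CR, 44 without BAT_1959_WT.

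EX changed 459 BAT genes, 158 up and 301 down. Without the number series term the split was 71 up and 236 down, with 232 of the genes shared. Genes of fatty acid and sterol synthesis rose: Acly, which makes cytosolic acetyl-CoA, rose (1.75 ± 0.40, adjusted p = 0.0142), fatty acid synthase, Fasn, rose (1.51 ± 0.37, adjusted p = 0.0207), and Aacs (1.53), Thrsp (1.02) and Fdps (1.13) rose with them. Genes of macrophages and of the extracellular matrix fell: Lgals3 fell (-1.86 ± 0.40, adjusted p = 0.009), the macrophage gene Ms4a7 fell by 1.34, the complement gene C1qb by 1.27 and Lum (-1.46 ± 0.25, adjusted p = 0.00185). Of 19 de novo lipogenesis genes 5 rose over all genes tested and 11 rose adjusted over the list alone (median 0.57, adjusted p = 6.3e-08, adjusted p = 0.229 with an estimated correlation). In cholesterol synthesis, 4 rose over all genes tested and 5 rose and 1 fell adjusted over the list alone of 18, the enzymes Fdps, Nsdhl (0.98), Pmvk (0.91) and Lss (0.72) (median 0.24, adjusted p = 8.43e-05, adjusted p = 0.212 with an estimated correlation). Of 23 macrophage and antigen presentation genes 16 fell over all genes tested and 19 fell adjusted over the list alone, Tyrobp (-1.10) among them (median -0.87, adjusted p = 1.62e-15, adjusted p = 0.229 with an estimated correlation). In the list for collagen and extracellular matrix, 15 fell over all genes tested and 26 fell adjusted over the list alone of 30, such as Col5a1 (-1.16), Col6a1 (-1.08) and Col6a2 (-0.99) (median -0.66, adjusted p = 8.02e-18, adjusted p = 0.0898 with an estimated correlation). Among heat shock genes 3 rose over all genes tested and 5 rose adjusted over the list alone of 17, namely Hspb1 (1.25), Hspb8 (0.82) and Stip1 (0.41) (median 0.30, adjusted p = 0.00162, adjusted p = 0.37 with an estimated correlation). Among immediate early genes 3 fell over all genes tested and 6 fell adjusted over the list alone of 21, namely Dusp1 (-1.12), Junb (-0.82) and Socs3 (-0.40) (median -0.27, adjusted p = 0.00271, adjusted p = 0.37 with an estimated correlation).

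Further BAT genes that fell after EX were the cell cycle genes Ccnd1 (-1.41), Prc1 (-0.74, detected on 3 EX arrays) and Hmgb2 (-0.41). The endothelial genes Plvap (-0.98) and Aplnr (-0.71, 5 EX arrays) and the interferon gene Bst2 (-0.96) fell too. Cell cycle genes, endothelial and angiogenesis genes and interferon response genes shifted down (medians -0.22, -0.26 and -0.25, adjusted p = 0.0157, 0.00646 and 0.00235, or 0.352, 0.49 and 0.53 with an estimated correlation, with 3, 2 and 1 members past the threshold). Cd52 (-1.27) and Coro1a (-0.99), each on the lower side on 5 of 6 arrays, fell among lymphocyte genes. In BAT, lymphocyte genes shifted down (median -0.29, adjusted p = 0.0212, or 0.646 with an estimated correlation, with 2 members past the threshold). Sncg (-1.32) and the glycerol channel gene Aqp7 (-0.84) fell and Lpin1 rose (0.66) among adipocyte lipid storage genes. The list for adipocyte lipid storage genes shifted down (median -0.16, adjusted p = 0.0442, or 0.448 with an estimated correlation, with 3 members past the threshold). Of 9 fat expansion markers 0 changed over all genes tested and 5 fell adjusted over the list alone in limma, and 0 lay above 0 (median -0.43, adjusted p = 0.00148, adjusted p = 0.229 with an estimated correlation). Slamf9 (-1.32), Lhfpl2 (-1.29) and haptoglobin, Hp (-1.23), fell, and Gldn (1.53), the carbonic anhydrase Car14 (1.42), Aspg (1.20), Tppp (1.15) and Rbp4, the retinol carrier of plasma (1.58), rose. Fast fibre genes and hepatocyte genes shifted up (medians 1.74 and 0.56, adjusted p = 0.0138 and 0.00294, or 0.743 and 0.468 with an estimated correlation, with 0 and 1 members past the threshold). Fast fibre levels were high on BAT_1970_EX and BAT_1972_EX. Without the 4 BAT arrays high in these genes 103 rose and 217 fell, and the shifts of fast fibre genes, hepatocyte genes, endothelial and angiogenesis genes and adipocyte lipid storage genes did not pass (adjusted p = 0.871, 0.0954, 0.075 and 0.12). The thermogenic and brown adipocyte genes showed a median of -0.02 and a mean of 0.07 (adjusted p = 0.501). List calls ended for lymphocyte genes (series A), adipocyte lipid storage genes (fixed slide, 7 of 14 and 5 of 12), heat shock genes (fixed slide) and cell cycle genes (median scaling). The BAT EX count was 183 (157 shared) within series A and 456 with slide as a random block. It was 144 with slide as a fixed term (60 up, 84 down), in a joint fit giving 190 without it. Without BAT_1961_WT there were 250 and without BAT_1974_EX there were 278.

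In SIRT1Tg eWAT 7 of 11791 genes passed, 2 up and 5 down. Cd8b1, a coreceptor chain of cytotoxic T cells, fell (-1.99 ± 0.36, adjusted p = 0.0292), and the leukocyte genes Lat2 (-1.0), Cx3cr1 (-0.91), Sirpb1a (-0.90) and Cd180 (-0.77) fell too. The pseudokinase gene Trib2 rose (0.77 ± 0.15, adjusted p = 0.0451) beside Sirt1. All 7 lay on the fitted side on each of the 6 arrays; Cx3cr1, Sirpb1a and Cd180 were detected on 4 of the SIRT1Tg arrays. With the matrix values these 3 were at -0.16, -0.18 and -0.12, and Cd8b1 (-0.93), Cx3cr1 and Cd180 did not pass. Of 18 lymphocyte genes 1 fell over all genes tested and 14 fell adjusted over the list alone, 0 members were above 0 (median -1.01, adjusted p = 3.78e-18, adjusted p = 0.162 with an estimated correlation). For macrophage and antigen presentation genes, 0 changed over all genes tested and 2 fell adjusted over the list alone of 25 (median -0.36, adjusted p = 1.91e-06, adjusted p = 0.422 with an estimated correlation). In eWAT, interferon response genes and cell cycle genes shifted down (medians -0.16 and -0.15, adjusted p = 0.015 and 0.0415, or 0.743 and 0.516 with an estimated correlation). The lists for endothelial and angiogenesis genes, heat shock genes and mesothelial genes shifted up (medians 0.23, 0.25 and 0.41, adjusted p = 1.16e-05, 0.00271 and 0.00869, or 0.413, 0.229 and 0.53 with an estimated correlation). Hepatocyte genes and erythroid genes shifted up (medians 0.26 and 0.18, adjusted p = 0.0132 and 0.0493, or 0.57 and 0.579 with an estimated correlation). Other scalings gave other splits, 2 rises and 2 falls with the deposited matrix values and 1 rise and 5 falls with median scaling. The epididymis genes were over 0.5 above the tissue median on WAT_1953_SiRT1, WAT_1955_SiRT1, WAT_1960_WT and WAT_1961_WT, and without the 8 such eWAT arrays 71 genes rose and 208 fell and the shift of hepatocyte genes did not pass (adjusted p = 0.0688). In eWAT, calls ended for cell cycle genes (series A, fixed slide, median scaling), erythroid genes (series A, fixed slide, median scaling, 7 of 15 and 4 of 12) and mesothelial genes (series A). So did those for interferon response genes (series B), hepatocyte genes (series B) and heat shock genes (fixed slide). The eWAT SIRT1Tg count was 1 (1 shared) within series A, 24 (6 shared) within series B and 3 with slide as a random block. It was 7 with slide as a fixed term (2 up, 5 down), in a joint fit giving 67 without it. The number followed single eWAT arrays: 1 without WAT_2222_SiRT1 or WAT_2228_WT, 3 without WAT_1953_SiRT1 or WAT_2223_SiRT1, 11 without WAT_1960_WT, 12 without WAT_1955_SiRT1, 24 without WAT_1961_WT.

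CR changed 427 eWAT genes, 87 up and 340 down. The split was 213 up and 218 down without the number series term, with 253 of the genes shared, and 201 up and 295 down without WAT_2241_CR. The macrophage elastase gene Mmp12 fell (-2.26 ± 0.37, adjusted p = 0.00229, -0.65 with the matrix values), Gpnmb (-1.91 ± 0.34, adjusted p = 0.00306), and Trem2, a receptor of lipid-laden macrophages, by 1.65 (adjusted p = 0.00259). Genes of fatty acid synthesis rose: the elongase Elovl6 rose (2.93 ± 0.46, adjusted p = 0.00166), Acly (1.40 ± 0.24, adjusted p = 0.00253) and Aacs by 0.95. Angptl8, an inhibitor of lipoprotein lipase made by fed adipocytes, rose (1.91 ± 0.34, adjusted p = 0.00339), and the clock output gene Dbp rose (1.91 ± 0.48, adjusted p = 0.0262). Of 25 macrophage and antigen presentation genes 17 fell over all genes tested and 23 fell adjusted over the list alone (median -1.25, adjusted p = 3.66e-24, adjusted p = 0.106 with an estimated correlation). Of 18 lymphocyte genes 7 fell over all genes tested and 9 fell adjusted over the list alone, among them Nkg7 (-1.52), Cd8b1 (-1.49), Cd3d (-1.43) and Il7r (-1.35) (median -1.0, adjusted p = 2.14e-10, adjusted p = 0.32 with an estimated correlation). In de novo lipogenesis, 3 rose over all genes tested and 12 rose adjusted over the list alone of 20 and all 20 were above 0 (median 0.83, adjusted p = 1.58e-10, adjusted p = 0.0898 with an estimated correlation). In cholesterol synthesis, 3 rose over all genes tested and 3 rose adjusted over the list alone of 18, namely Pmvk (1.05), Nsdhl (0.89) and Cyp51 (0.84) (median 0.42, adjusted p = 0.000275, adjusted p = 0.229 with an estimated correlation). In the circadian clock list 5 rose over all genes tested and 5 rose adjusted over the list alone of 19, with Bhlhe40 (1.41), Nr1d2 (0.99) and Tef (0.89) beside Dbp and a median of 0.39 (adjusted p = 0.000956, adjusted p = 0.212 with an estimated correlation). For oxidative phosphorylation, 6 rose and 1 fell over all genes tested and 26 rose and 1 fell adjusted over the list alone of 58; Ndufs4 (0.52), Ndufs8 (0.51) and Ndufa5 (0.49) rose, Cox6a2, the subunit of striated muscle, fell (-0.71, detected on 4 WT and 2 CR arrays) (median 0.29, adjusted p = 1.85e-17, adjusted p = 0.104 with an estimated correlation).

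In the list for collagen and extracellular matrix, 3 fell over all genes tested and 9 fell adjusted over the list alone of 31 in eWAT under CR. These were Acta2 (-1.47), Tgfb1 (-0.51) and Thbs1, detected on 6 WT and 0 CR arrays and at least 2.41-fold lower with its CR arrays set at their detection floor (adjusted p = 0.00379; fitted -1.34, and -0.24 with the matrix values); the list median was -0.48 (adjusted p = 1.21e-07, adjusted p = 0.393 with an estimated correlation). Of 25 cell cycle genes 3 fell over all genes tested and 4 fell adjusted over the list alone, namely Cenpa (-1.03), Mcm5 (-0.62) and Tk1 (-0.61) (median -0.26, adjusted p = 0.000854, adjusted p = 0.337 with an estimated correlation). In acute phase and innate inflammation, Saa3 (-2.33) and Cxcl10 (-0.90, detected on 4 CR arrays) fell; 2 fell over all genes tested and 5 fell adjusted over the list alone of 24 (median -0.09, adjusted p = 0.0212, adjusted p = 0.388 with an estimated correlation). Atf3 (-1.57, 3 CR arrays) fell among immediate early genes. In eWAT, immediate early genes and interferon response genes shifted down (medians -0.33 and -0.29, adjusted p = 0.000649 and 0.00102, or 0.413 and 0.617 with an estimated correlation, with 1 and 0 members past the threshold). Other named falls were the muscle actin Acta1 (-2.64), Serpina3b (-2.33, 5 CR arrays), the chemokines Ccl8 (-1.93) and Ccl9 (-1.81), Ubd (-1.90), Rgs1 (-1.85, 1 CR array, -0.46 with the matrix values), Slc15a3 (-1.77) and the macrophage gene Ms4a7 (-1.60). Parm1 (1.67), Tmem79 (1.64), Fn3k (1.34), Esm1 (1.34) and the vitamin transporter gene Slc5a6 (1.21) rose. All 44 named genes past the threshold lay on the fitted side on each of the 6 arrays. Epididymis genes were at 8.75 on WAT_2241_CR against 4.46 to 4.56 on the other CR arrays, and without the 8 eWAT arrays high in them 641 genes rose and 786 fell. List calls ended for acute phase and innate inflammation (median scaling). The eWAT CR count was 620 (373 shared) within series B and 407 with slide as a random block. It was 444 with slide as a fixed term (152 up, 292 down), in a joint fit giving 512 without it. Without WAT_2232_WT there were 177 and without WAT_2228_WT there were 208.

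**Figure D3:**
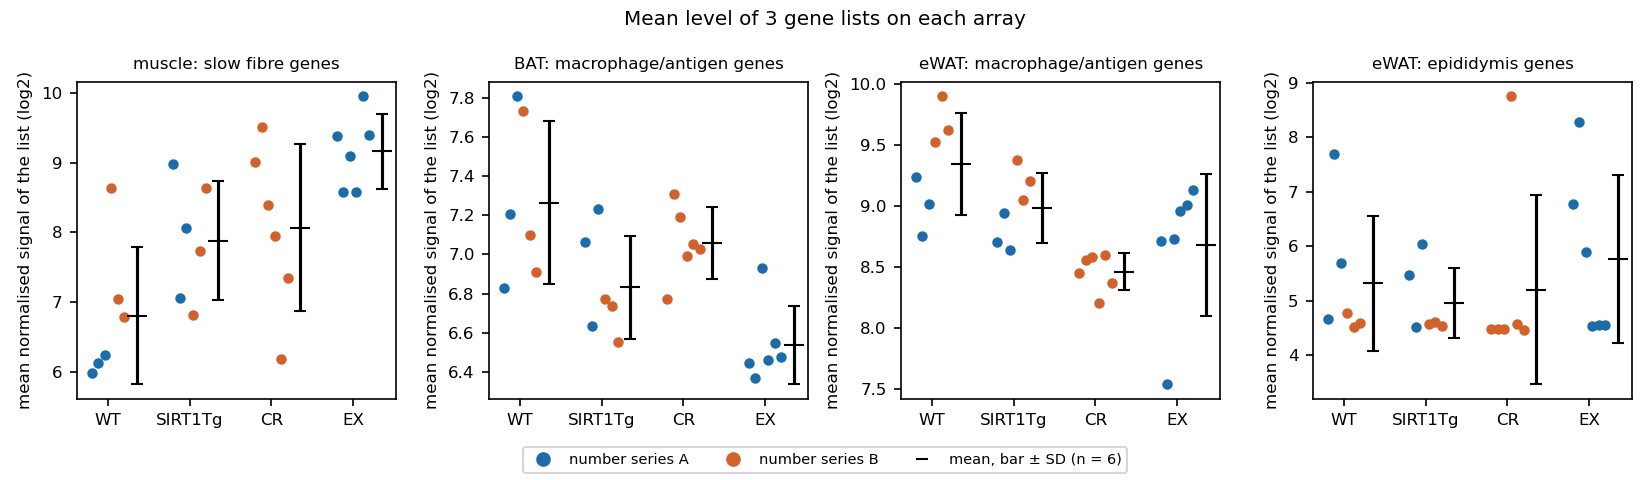
Mean normalised signal (log2) of the members of 3 gene lists on each array: slow fibre genes in muscle, macrophage and antigen presentation genes in BAT and in eWAT, and epididymis genes in eWAT. Points are arrays coloured by number series and bars are the mean ± SD of 6 arrays.

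After EX, 1 of 11791 eWAT genes passed. Cd180, a receptor of B cells and myeloid cells, fell (-0.87 ± 0.14, adjusted p = 0.0301) and was detected on 2 EX arrays. It did not pass with the matrix values (-0.14), without background correction (-0.24), with an offset of 50 (-0.40) or with median scaling (-0.76). The genes of next smallest p, H2ac12 (-0.74), H2ac7 (-0.78), Lat2 (-0.79) and Lrrc20 (-0.53), each had an adjusted p of 1. The fat expansion markers had a median of -0.88 with 0 of 10 above 0; 0 changed over all genes tested and 0 changed adjusted over the list alone in limma (adjusted p = 0.000588, adjusted p = 0.448 with an estimated correlation). The lists for macrophage and antigen presentation genes, lymphocyte genes and collagen and extracellular matrix shifted down (medians -0.35, -0.48 and -0.31, adjusted p = 6.25e-08, 2.27e-06 and 8.89e-05, or 0.37, 0.413 and 0.527 with an estimated correlation). Cell cycle genes and Schwann cell and myelin genes shifted down (medians -0.11 and -0.27, adjusted p = 0.00235 and 0.0422, or 0.37 and 0.229 with an estimated correlation). In eWAT, hepatocyte genes, oxidative phosphorylation, ER stress and integrated stress response and de novo lipogenesis shifted up (medians 0.85, 0.05, 0.11 and 0.18, adjusted p = 8.96e-09, 0.00626, 0.0164 and 0.0485, or 0.229, 0.57, 0.393 and 0.53 with an estimated correlation). Epididymis gene levels were high on WAT_1966_EX, WAT_1971_EX and WAT_1972_EX, and without the 8 such eWAT arrays 5 genes rose and 44 fell, while the shifts of macrophage and antigen presentation genes (adjusted p = 0.135), collagen and extracellular matrix (adjusted p = 0.714) and hepatocyte genes (adjusted p = 0.354) did not pass. WAT_1971_EX stood at 7.54 for macrophage and antigen presentation genes, against 8.71 to 9.13 on the other 5 EX arrays, and at 7.69 for collagen and extracellular matrix, against 8.82 to 9.23. Without that array the medians were -0.15 (adjusted p = 0.0438) and -0.06 (adjusted p = 0.589). Under median scaling the test of oxidative phosphorylation turned downward with a list mean of 0.04. At unadjusted p under 0.05 there were 487 genes against 589.6 by chance. Recovery in simulated data, 82.1% at 2-fold and 43.3% at 1.5-fold, need not hold here. In eWAT, calls ended for de novo lipogenesis (series A, random slide, median scaling, 5 of 14 and 4 of 12), Schwann cell and myelin genes (series A, median scaling, 7 of 13 and 4 of 12), oxidative phosphorylation (median scaling) and ER stress and integrated stress response (median scaling). The eWAT EX count was 0 (limma, with 170 at unadjusted p under 0.05) within series A and 1 with slide as a random block. It was 3 with slide as a fixed term (1 up, 2 down), in a joint fit giving 1 without it. Cd180 lost its call in limma, with 0 without WAT_1959_WT, WAT_1961_WT, WAT_2226_WT, WAT_2228_WT, WAT_2232_WT, WAT_1971_EX, WAT_1975_EX, WAT_1972_EX or WAT_1974_EX, at 388 to 802 genes of unadjusted p under 0.05.

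Differences between the 4 tissues were tested gene by gene over 13616 genes. The SIRT1Tg effect differed for 28 genes, the CR effect for 334 and the EX effect for 104. Sfxn1 differed most in SIRT1Tg mice, at -2.77 in BAT, 0.02 in liver, -0.28 in muscle and -0.14 in eWAT (adjusted p = 2.82e-14). F11 was -0.97 in liver and 0.01 to 0.03 elsewhere (adjusted p = 2.18e-06). Under CR, Plin4 stood at -1.97 in liver and -0.06 in BAT (adjusted p = 2.87e-06), and Mmp12 at -1.86 in eWAT and 0.23 in liver (adjusted p = 7.6e-06). After EX, Saa1 stood at -2.98 in liver and 0.20 in BAT (adjusted p = 1.59e-06), and Myl3 at 6.52 in muscle and 0.95 in BAT (adjusted p = 0.000437). Without the series term the EX count was 280, and with the matrix values the SIRT1Tg count was 74. Sirt1 rose in 3 tissues of SIRT1Tg mice, and Pdk4 fell under CR in liver, BAT and eWAT. Muscle and BAT shared 5 rises after EX (1.78 in independent lists) and 3 falls (2.07), and 2 genes moved in opposite directions.

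Fold changes of 2 interventions in the same tissue share their WT arrays, so their correlation across genes, which are not independent replicates, was set beside that of 200 simulations with no effect. Over the 12 pairs the correlation ran from -0.0961 to 0.535, each inside the simulated range. SIRT1Tg and EX correlated at 0.535 in muscle against a simulated mean of 0.421, with a covariance of 0.0286 against 0.011, and at 0.0189 when no WT array was shared. CR and EX correlated at 0.376 in eWAT against 0.109, with a covariance of 0.0307 against 0.00844, and at 0.238 with no shared array. In BAT, 17 genes fell in both SIRT1Tg and EX, where independent lists would share 0.751, among them Lum, Sncg, Cd63, Cyba, Casp1, Slamf9 and Lgals3bp, and 1, Hk2, rose in both. In eWAT, Cd180, Cd8b1, Lat2 and Sirpb1a fell in both SIRT1Tg and CR, where 0.144 would be shared. With no effect put in, 100 simulations cannot test these overlaps: shared falls numbered 0 in BAT and 0 to 188 in eWAT (mean 1.88). With WT arrays split by series, each pair shared 0 calls. Calls were 3 SIRT1Tg and 425 EX in BAT and 2 SIRT1Tg and 374 CR in eWAT. So few SIRT1Tg calls leave little to share (0.0503 and 0.0263 falls in independent lists). All 18 genes in BAT and 4 in eWAT kept their side, but were selected on these arrays. The overlaps may come in part from shared WT arrays.

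Of the 300 combinations of list, tissue and comparison with 5 or more measured members, 107 passed in camera with a preset correlation of 0.01, and 0 passed with a correlation estimated from the data (lowest adjusted p = 0.0898). No called list had a median, mean and test of different sign, and 41 of the others did. With slide as a random block 110 passed, and with slide as a fixed term 98 of 261 did. The sirtuins and NAD metabolism had 0 calls in 12 combinations (lowest adjusted p = 0.112, BAT of SIRT1Tg), although Sirt1 belongs to them. The thermogenic and brown adipocyte genes had none in 6 (lowest adjusted p = 0.07, BAT under CR), and genes of gluconeogenesis and amino acid catabolism had none in liver (lowest adjusted p = 0.116, EX). The exocrine pancreas genes (lowest adjusted p = 0.331) and epididymis genes (lowest adjusted p = 0.313), both lowest in eWAT under CR, had none either.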

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

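The tests of a slow muscle share, of low WT levels alone and of epididymis RNA were chosen after the results were seen; the label splits and the random removal of arrays were planned before their results. Among 616 sets of 6 values (detected probes, named genes and list levels per group) 51 held an array far from the other 5, and chance gives about 1 in 20. The array liver_1953_SiRT1 detected 5841 probes and read 4.48 for Sirt1, where the other 5 read 7.41 to 7.72. The array muscle_2241_CR detected 8427 probes, against 11327 to 12321 on the others, and read 5.25 for Sirt1. The BAT CR array of the same animal detected 12847 probes, with fast fibre genes at 11.63, and its eWAT array detected 15318, with epididymis genes at 8.75.

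Counted per array, BAT_1970_EX stood apart in 7 values, the levels of 4 lists (macrophage and antigen presentation genes, lymphocyte genes, cell cycle genes and hepatocyte genes) and of Cd52, Coro1a and Slamf9. WAT_2241_CR and liver_1953_SiRT1 did so in 5, muscle_2226_WT in 4 (Myl3, Tnnc1, Tnni1 and Lrrc52), BAT_1959_WT and BAT_1961_WT in 3, and BAT_1966_EX, BAT_2207_SiRT1, WAT_1971_EX and muscle_2241_CR in 2. In 1 value each the list holds BAT_2236_CR, BAT_2241_CR, BAT_2242_CR, BAT_1969_EX, BAT_1953_SiRT1, BAT_2222_SiRT1, BAT_2226_WT, WAT_1954_SiRT1, WAT_1955_SiRT1, WAT_2207_SiRT1, WAT_1960_WT, liver_2230_CR, liver_2236_CR, liver_1960_WT, muscle_1974_EX and muscle_1976_EX. Sfxn1 on BAT_1961_WT was among these values, at 11.90 against 11.17 to 11.36, and lies away from the SIRT1Tg level of 8.53 ± 0.37.

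Effects differed between tissues for 28 genes with SIRT1Tg, 334 with CR and 104 with EX, and among named genes for 3, 43 and 14. In splits of the animals into groups of the same sizes, 10 of 100 gave as many genes for SIRT1Tg (highest other 1067), 1 of 100 for CR, the real one (highest other 146), and 11 of 100 for EX (highest other 402). This argues against chance for CR, not SIRT1Tg or EX. Splits with 1067 and 402 genes point to a structure among the samples that the conditions do not explain.

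For the single tissues, only the real split of 100 reached the count in liver CR (27; highest other 2), muscle SIRT1Tg (3; 0), muscle EX (191; 41), BAT SIRT1Tg (39; 4), BAT CR (27; 8), BAT EX (459; 132), eWAT SIRT1Tg (7; 2) and eWAT CR (427; 23). This argues against chance, unadjusted over the tests. It does not exclude slide: CR and EX shared few slides with WT, and SIRT1Tg none in BAT and eWAT. There a fixed slide term took its joint fit from 20 to 2 and 67 to 7 genes. In liver EX 2 of 100 reached the count (2; 2), so chance is open. Chance cannot be excluded for liver SIRT1Tg, where 5 of 100 splits gave 6 or more (highest 1571), or for eWAT EX, where 10 of 100 gave 1 or more (highest 526). Splits cannot test muscle CR, since each reaches a count of 0 (limma; 578 at unadjusted p under 0.05; highest other 2). Splits with 1571 and 526 genes also point to structure among the arrays, whose source was not tested.

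Slow fibre genes were higher in muscle after EX. Low WT levels in the same number series are not the whole cause: EX lay 1.68 (log2) above the WT arrays of the other series, 4 of 6 EX arrays lay above every WT array, and the difference of 2.36 from all 6 had an exact two-sided permutation p of 0.00649. A larger share of slow muscle in the piece dissected may explain it: on the 18 arrays of other groups, 165 of 182 changed genes outside the list followed the slow fibre level in the direction of EX, with a median signed correlation of 0.476, where other genes had a median absolute one of 0.218. On the 12 SIRT1Tg and CR arrays, without WT, it was 0.487 with 161 above 0. The respiratory chain list kept its call with that level as a term (mean 0.19). With the term 0 genes passed (limma; 478 at unadjusted p under 0.05), since the level is itself higher after EX and the term takes up part of the effect. A shift of fibre type by training predicts the same values and stays open, untested.

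Few genes changed in eWAT after EX, and epididymis RNA on some arrays is a candidate cause. On 8 arrays from the 4 conditions epididymis genes read 5.47 to 8.75, against 4.46 to 4.78 on the other 16; 15 of the 18 genes were higher, by a median of 2.7. Without these 8 arrays 49 genes changed, with only WAT_1959_WT left of series A WT. Removing as many random arrays per group gave 31 or more genes, the count on the same normalised values, in 3 of 100 draws (highest 262), which argues against the smaller number of arrays. With the epididymis level as a term the EX count was 1, against a simple additive effect, and a weak eWAT response was not tested.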

How the results depend on the processing

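Array weights, the offset of 50, removal of arrays by detection or by genes of another tissue, and the terms for slow fibre, fast fibre and epididymis levels were chosen after the data were seen. Counts given here moved by over 1.5 times from those of the report, and no others did. The exception is slide as a fixed term, with all counts given. Where no reason is given, the cause was not tested. With the deposited matrix values the counts were 14 for liver SIRT1Tg, 0 for liver EX (878 unadjusted), 1 for muscle CR, 25 for BAT SIRT1Tg, 4 for eWAT SIRT1Tg and 0 for eWAT EX (483 unadjusted). Without background correction the counts were 0 for liver EX (870 unadjusted), 1 for muscle CR, 24 for BAT SIRT1Tg, 11 for eWAT SIRT1Tg and 0 for eWAT EX (474 unadjusted). Median scaling in place of quantile normalisation gave 21 for liver SIRT1Tg, 9 for liver CR, 84 for muscle EX, 16 for BAT CR and 0 for eWAT EX (622 unadjusted). No filter on detection, with 18312 features tested, gave 0 for liver SIRT1Tg (1457 unadjusted), 14 for liver CR, 0 for liver EX (1218 unadjusted), 88 for muscle EX and 20 for BAT SIRT1Tg. Restriction to probes detected on all arrays of a tissue, which tests fewer genes, gave 14 for liver SIRT1Tg, 1 for liver EX, 4 for eWAT SIRT1Tg and 0 for eWAT EX (339 unadjusted).

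Leaving out the number series term gave 54 for liver CR, 0 for liver EX (442 unadjusted), 12 for muscle CR, 686 for muscle EX and 3 for eWAT SIRT1Tg. Within number series A, with 3 WT arrays, the counts were 0 for liver SIRT1Tg (632 unadjusted), 1 for liver EX, 37 for muscle SIRT1Tg, 365 for muscle EX, 2 for BAT SIRT1Tg, 183 for BAT EX, 1 for eWAT SIRT1Tg and 0 for eWAT EX (170 unadjusted). Within number series B, with 3 WT arrays, the counts were 88 for liver CR, 1 for muscle SIRT1Tg, 2 for muscle CR, 2 for BAT SIRT1Tg, 13 for BAT CR and 24 for eWAT SIRT1Tg. Slide as a random block gave 7 for BAT SIRT1Tg and 3 for eWAT SIRT1Tg. Slide as a fixed term was put in the joint fit of 8290 genes (count without slide in brackets). For SIRT1Tg, CR and EX it gave 113 (132), 30 (47) and 37 (19) in liver and 2 (7), 4 (4) and 304 (205) in muscle. It gave 2 (20), 7 (12) and 144 (190) in BAT and 7 (67), 444 (512) and 3 (1) in eWAT.

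A normexp offset of 50 gave 0 for liver EX (876 unadjusted), 1 for muscle CR, 23 for BAT SIRT1Tg and 0 for eWAT EX (474 unadjusted). Array weights gave 60 for liver SIRT1Tg, 167 for liver CR, 0 for liver EX (669 unadjusted), 64 for muscle SIRT1Tg, 54 for muscle CR, 499 for muscle EX, 134 for BAT SIRT1Tg, 55 for BAT CR, 293 for eWAT SIRT1Tg and 1286 for eWAT CR. Removing the array of low detection in the tissue gave 21 for liver SIRT1Tg, 6 for muscle SIRT1Tg and 426 for muscle EX. The slow fibre level as a term gave 0 for muscle EX (478 unadjusted). The fast fibre level as a term gave 22 for BAT SIRT1Tg. Removing the BAT arrays high in fast fibre genes gave 7 for BAT CR. The epididymis gene level as a term gave 134 for eWAT SIRT1Tg and 730 for eWAT CR. Removing the 8 eWAT arrays high in epididymis genes gave 279 for eWAT SIRT1Tg, 1427 for eWAT CR and 49 for eWAT EX. The slow fibre level is itself higher after EX, so its term takes up part of the EX effect by construction.

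Leaving out single arrays gave counts of 0 to 21 for liver SIRT1Tg, 5 to 42 for liver CR, 0 to 3 for liver EX, 2 to 3 for muscle SIRT1Tg, 0 to 2 for muscle CR, 2 to 254 for muscle EX, 4 to 157 for BAT SIRT1Tg, 9 to 44 for BAT CR, 250 to 603 for BAT EX, 1 to 24 for eWAT SIRT1Tg, 177 to 496 for eWAT CR and 0 to 1 for eWAT EX.

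Liver Sirt1 passed the threshold with median scaling (1.08), within number series B (1.41), with array weights (1.38), without the array of low detection (1.38) and with slide as a fixed term (0.87), and BAT Sirt1 lost its call with slide as a fixed term (1.11). Leaving out single arrays gave Sirt1 differences of 0.71 to 1.38 in liver, 1.78 to 1.89 in muscle, 1.32 to 1.43 in BAT and 2.52 to 2.64 in eWAT. Myl2 (-0.082), Myoz2 (-0.093) and Smtnl1 (-0.063) reversed after EX with the slow fibre term, and no other named gene past the threshold reversed. Sirt1 under CR or EX, never past the threshold, changed sign between alternatives in liver EX, BAT EX and both eWAT comparisons.

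Of 205 named genes, 177 kept their side of the threshold with the matrix values, 171 without background correction, 158 with median scaling, 134 with no filter on detection, 150 without the number series term and 181 with slide as a random block, 92 of 149 with slide as a fixed term, 64 of 117 within series A and 81 of 125 within series B, and with single arrays left out 1744 of 2460 pairs of gene and array did.

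List calls numbered 107, and 0 with an estimated correlation (lowest adjusted p = 0.0898); the other alternatives over all lists gave 85 to 110. The list test reversed (list means in brackets) for oxidative phosphorylation in liver SIRT1Tg (-0.018) and in eWAT EX (0.041), both with median scaling. It reversed for macrophage and antigen presentation genes in liver SIRT1Tg within series A (-0.082). With the slow fibre term it did so for fatty acid oxidation and PPAR targets in muscle SIRT1Tg (0.0077) and EX (-0.043) and for glucose uptake and endurance genes in muscle EX (-0.015). In eWAT SIRT1Tg it did so for erythroid genes within series A (-0.17) and hepatocyte genes within series B (0.00064).

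With the animal number as replicate block, which uses the pairing of tissues, effects differed between tissues for 37 genes with SIRT1Tg, 356 with CR and 129 with EX, and these included the 28, 334 and 104 of the report. The consensus correlation within animals was 0.035, and the block moved none of these 3 counts by over 1.5 times. The matrix values gave 74 for SIRT1Tg, and leaving out the number series 280 for EX. With no shared WT arrays the correlation of fold changes turned to -0.203 for SIRT1Tg and CR in liver, -0.0417 for SIRT1Tg and EX in liver, -0.0048 for SIRT1Tg and CR in muscle and -0.0572 for SIRT1Tg and CR in eWAT, and fell to 0.0189 for SIRT1Tg and EX in muscle. Signal over background limits what could be detected, from 5841 to 15381 probes per array.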

Other observations

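The tests of Dnajc12 and the choice of the genes in the next paragraph were made after their values were seen. Dnajc12, the gene next to Sirt1 in the annotation with 0 genes between them, was higher in SIRT1Tg in the 4 tissues, by 0.59 in liver, 0.67 in muscle, 0.54 in BAT and 1.05 in eWAT, past the threshold in muscle only (adjusted p = 0.589, 0.00332, 0.0666 and 0.0592). By its lowest effect it ranked 9 of 8290 genes measured in the 4 tissues, and whether Dnajc12 was carried or changed with the transgene stays open, a hypothesis that the rank does not settle. Herc4, on the same chromosome, differed by 0.11 to 0.29. Of the 40 nearest measured genes 4, or 10%, had a mean effect in the outer 5% of genes, which leaves a longer stretch of the chromosome open.

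Genes outside the naming rule also differed between tissues. With CR, Cd84 (-1.75), Dpep2 (-1.44) and Ciita (-1.43) were lower in eWAT. After EX, Casq2 (1.52) and Il15 (0.96) were higher and Fgf6 (-0.74) lower in muscle.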
